A study of Mus musculus with 65 samples.

How the data were processed

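The values analysed were the count tables of genes and of repeat copies as deposited by the authors, who made them from RNA sequencing reads by alignment and counting before deposit (STAR, HOMER, mm10, and DESeq2 per the submitters' processing notes, without version numbers). The labels name a polyA TruSeq Stranded kit. All 65 libraries were used, in 19 groups, and no column was left out. Reads were not analysed here. Replicates carry cohort numbers, and in the wild-type groups of experiment 3 up to 2 libraries share a title and a cohort number. It is not given whether such libraries come from the same cells, and every library was counted as separate.

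The gene table held 23755 symbols (2824 with 0 counts in all libraries), of which 23034 have a name in GENCODE mouse release 21, a copy whose build may not be the one the authors used. The repeat table held 3725827 copies with 1153 names. Those of the classes LINE, SINE, LTR, DNA and RC, without names that carry a question mark in class or family (3649575 copies, 1382602 with counts), were summed into 1057 subfamilies. Of the counts on repeats 44.95% lay on SINE, 32.2% on LTR, 15.1% on LINE and 4.2% on DNA elements. TEs had a median of 2.68 M counts per library. The repeat table carries running numbers and no coordinates, so overlap of copies with genes was not analysed here, and the rule on gene spans for naming copies was not applied. Myd88 neighbours were placed with GENCODE.

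Each experiment was fitted on its own with edgeR 4.0.16 (R 4.3.3): low counts were removed with filterByExpr, libraries were scaled by TMM, and quasi-likelihood F tests were made on a model with 1 term per group. All adjusted p for genes, subfamilies and copies are from edgeR with the Benjamini-Hochberg method, and 0.05 was the threshold. Errors beside log2 fold changes are standard errors, taken as the fold change divided by the root of F. Errors beside CPM and percentages are standard deviations. The prior count of log CPM was 2. This left 14386, 14475 and 13078 genes in experiments 2, 3 and 5. Subfamilies and copies were scaled by the gene totals and the TMM factors of the genes, and tested in the same way (943, 945 and 937 subfamilies). Copies needed 10 counts in 3 libraries (59202, 64924 and 63366 copies). Responses to LPS were compared as differences of log2 fold changes within the same fit. Shares of counts were compared by a two-sided exact permutation of libraries between the groups.

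The 23 gene lists were fixed before the data were examined, as were the comparisons, filters, thresholds and the rule for naming genes. Each list was tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists of a comparison), and again with a correlation estimated from the data, an alternative added later. Members were also adjusted over their list alone. Il12b, Setdb2, Rlf, Ly6g, Ighm, Igkc, Trac, Trbc2 and Hbb-b1 were not in the gene table and are not analysed here.

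The text names genes by a rule: the targets Myd88, Ticam1, Suv39h1 and Ifnar1 in every library; up to 4 members per list with the largest absolute log2 fold change past the threshold; up to 2 members that did not pass of the cytokine, interferon, IRF3 target, sensor and silencing lists; and the 6 largest rises and 6 largest falls with a mean of at least 5 CPM in the higher group and no overlap between groups, passing over predicted and small RNA genes. Overlap was not asked of differences of responses. Of subfamilies the 6 largest rises and falls past the threshold with at least 50 counts per library were eligible. From these, the genes with a known function were described. Folds from a group at 0 counts in every library were not printed. Genes outside the rule are named where they check a label (Xist) or stand in a result already given.

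Alternatives were DESeq2 1.42.0, no filter on low counts, only the compared groups in the fit, the cohort number as a replicate block, 1 library left out at a time, a term for the library sets, wild-type libraries of a cohort summed, TMM factors from the repeat table, and copies with 5 counts. Added after the first results were seen were the replicate block of set and cohort, each library set alone, subfamilies without their 10 copies with most counts, responses against the wild-type response of the same set, and camera with an estimated correlation. The 10 copies were those with most counts over all libraries of the experiment, so copies that rose strongly were more likely to be left out. A smaller or lost rise without them is therefore partly built in. The cohort number pairs some libraries: the residuals of libraries of the same cohort had a mean correlation of 0.451 within experiment 2 (-0.222 otherwise), 0.589 in MyD88KO cells and 0.454 in wild-type cells of the same set. It was 0.129 in TrifKO cells and 0.123 in experiment 5, where the block is hardly a pairing. The blocked value is therefore given where it moved a count.

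Of 88 pairs of libraries of a group, none was a duplicate (lowest chi-square per degree of freedom 5.08). Wild-type replicates 1b and 2b, of different cohort numbers, were the closest wild-type pair at every time. They gave 16.9, 10.5 and 13.6 at 0 h, 2 h and 4 h, against 39.1 to 388 for the other wild-type pairs. TrifKO libraries gave 6.53 to 21.1 at 0 h, and replicates 1 and 2 gave 25.7 and 25.6 at 2 h and 4 h. Whether such close libraries share cells is not given. The fit was tested on simulated data: of genes changed 2-fold it recovered 79.1% for wild-type cells at 4 h, 44.8% for the MyD88KO difference at 4 h and 56.7% for Suv39h1KO, and of copies changed 2-fold in Suv39h1KO 4.48%, so small changes of single copies are missed. Overlaps of knockouts or guides that share control libraries were set against simulated unchanged groups (8 and 10 draws). Groups were exchanged in up to 25 drawn splits. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.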

Results

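Gene and repeat transcript counts were available for 65 polyA RNA sequencing libraries of mouse cells, in 19 groups of 3 separate experiments. Experiment 2 held 12 libraries of unstimulated bone marrow derived dendritic cells, 3 in each of 4 groups: wild type, Suv39h1KO, IfnarKO, and both knockouts together. Experiment 3 held 35 libraries of the same cell type before and at 2 h and 4 h after 100 ng/mL lipopolysaccharide (LPS), the ligand of TLR4. Its wild-type groups had 6, 5 and 6 libraries, up to 2 for each of 3 cohort numbers, and its MyD88KO and TrifKO groups had 3 each. Whether wild-type libraries with the same cohort number share cells is not given, so p-values that count each as separate may be too small. Experiment 5 held 18 libraries of RAW264.7 cells, a mouse macrophage line, that carried a control guide RNA or either of a pair of other guides, at 0 h and 2 h, with 3 in each of 6 groups. The titles of these 18 libraries call the cells dendritic cells, while the source label names RAW264.7, which is used here. The labels do not give the genes that these guides target. The total count on genes was 36.9 M to 95.3 M per library, with a median of 54.7 M. Transposable elements (TEs: LINE, SINE, LTR, DNA and RC classes) had 1.66 M to 4.19 M counts per library, which was 3.32% to 5.69% of the counts on genes and TEs together.

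The targeted genes were read first, in every library. Suv39h1, which encodes a histone methyltransferase of heterochromatin, lay between 0.11 and 0.37 CPM (counts per 1e6 gene counts) in the 6 Suv39h1KO libraries and between 36.9 and 64.6 in the other 6 libraries of experiment 2. Ifnar1, a subunit of the type I interferon receptor, was still transcribed in IfnarKO cells, at 122 to 161 CPM in 6 libraries against 173 to 218 in the 6 others. Myd88, the adaptor of most Toll-like receptors, averaged 47.7 ± 1.28 CPM (SD, n = 3) in unstimulated MyD88KO cells and 75.1 ± 3.25 (n = 6) in wild-type cells. After LPS it averaged 101 and 293 CPM at 2 h and 92.0 and 421 CPM at 4 h in these genotypes. The files do not give the deleted parts of Ifnar1, Myd88 and Ticam1, so the transcripts left of Ifnar1 and Myd88 do not test the labels.

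Ticam1, the gene of TRIF, lay at 29.8 to 50.3 CPM in all 6 TrifKO libraries of cohorts 1 and 2, no lower than in wild-type cells (27.1 to 35.6 CPM at 0 h, 33.6 ± 6.59 with n = 5 at 2 h and 31.8 to 58.4 at 4 h). In cohort 3 it was 2.94 CPM at 2 h and 2.46 CPM at 4 h, but 31.7 CPM in the library labelled TrifKO 0h replicate 3. Xist, the transcript of the inactive X chromosome in females, was 1010 CPM in that library and at most 0.0204 CPM in the other cohort 3 TrifKO libraries. Xist also differed within TrifKO cohort 1 (0 CPM at 0 h and 2 h, 1233 at 4 h) and cohort 2 (1091 at 0 h, 1203 at 2 h, 0.0378 at 4 h). Either the TrifKO cohort numbers do not mark single animals or labels were exchanged, such as those of replicates 1 and 2 at 4 h, and this was not resolved. Every TrifKO response below was computed with the library labelled TrifKO 0h replicate 3 among its 3 baseline libraries. By these Xist values TrifKO cells had more female libraries at 0 h (mean 701 CPM) than at 2 h and 4 h (401 and 411 CPM). TrifKO responses and their differences from other genotypes therefore also hold a change in sex make-up, whose effect was not tested.

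**Figure D1:**
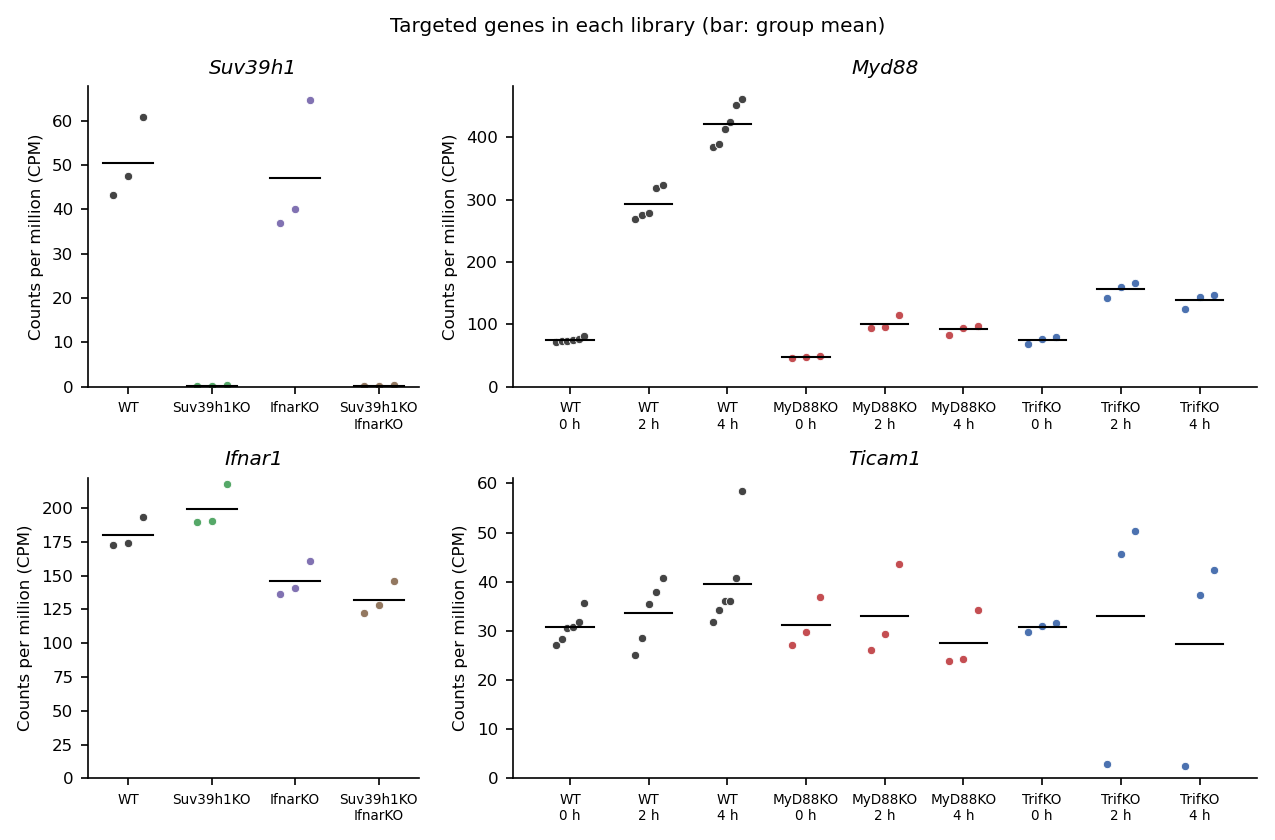
CPM of Suv39h1, Ifnar1, Myd88 and Ticam1, with 1 point per library and the groups of each experiment along the horizontal axis. Suv39h1 was at most 0.37 CPM in its knockout, while Ticam1 was low in TrifKO cohort 3 after LPS only (2.94 and 2.46 CPM).

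LPS switched on the inflammatory programme of wild-type dendritic cells within 2 h (5 libraries against 6). Ptgs2, which encodes an inducible cyclooxygenase, rose by 8.09 ± 0.47 (log2, SE). The neutrophil chemokine gene Cxcl1 rose by 8.04 ± 0.40, and Cxcl10, a chemokine gene driven by interferon, rose by 6.97 ± 0.36. Il23a rose by 9.73 ± 0.60 from a mean of only 0.0618 CPM, and Ifnb1, the interferon-beta gene, rose by 7.75 ± 0.52 from 0.05 CPM. By 4 h (6 against 6) Nos2, the inducible nitric oxide synthase gene, had risen by 9.45 ± 0.83 and Ptgs2 by 8.81 ± 0.48. The lysophosphatidic acid receptor gene Lpar5 fell at 2 h (-3.77 ± 0.46) and at 4 h (-5.17 ± 0.47), and Neurl1b fell by 4.32 ± 0.25 at 4 h. In all, 6641 of 14475 genes passed an adjusted p of 0.05 at 2 h (3083 higher, 3558 lower) and 9426 at 4 h (4347 higher, 5079 lower).

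Of 23 inflammatory cytokine and chemokine genes, 22 rose at 2 h and at 4 h, and 22 did so adjusted over the list alone. The list passed the camera test at both times (adjusted p = 3.24e-23 and 3.82e-15), and at 2 h also with an estimated correlation (adjusted p = 0.0285 at 2 h, adjusted p = 0.0903 at 4 h). Vegfa did not pass at either time (0.01 ± 0.16 and 0.16 ± 0.15). Of 26 NF-kB feedback and early genes, 24 rose at 2 h (24 adjusted over the list alone), with Nfkbiz at 5.58 and Socs3 at 5.45. At 4 h 21 rose and 1 fell (23 adjusted over the list alone; camera adjusted p = 2.04e-10, adjusted p = 0.0903 with an estimated correlation). All 42 interferon-stimulated genes (ISGs) that were tested rose at 2 h and at 4 h, all 42 also adjusted over the list alone. Ifi205 reached 7.79 and Oasl1 7.29 at 4 h, where the list's median was 5.05 (camera adjusted p = 1.36e-27, adjusted p = 0.0903 with an estimated correlation). The 7 type I interferon and IRF3 target genes all rose at both times (7 adjusted over the list alone), among them Ifit1 (7.07 ± 0.50) and Isg15 (6.85 ± 0.41) at 4 h. Their camera adjusted p at 4 h was 2.4e-07, and adjusted p = 0.0903 with an estimated correlation.

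Sensors of foreign nucleic acids and antigen presentation genes rose as well. At 2 h 13 sensor genes had risen and 2 fallen, and 16 maturation and 17 MHC class I genes had risen (17, 18 and 17 called when adjusted over the list alone). At 4 h, of 18 nucleic acid sensor and antiviral enzyme genes, 15 rose and 3 fell (18 adjusted over the list alone), with Ifih1, the gene of the RNA sensor MDA5, at 5.25 and Zbp1 at 5.12. The camera adjusted p was 1.57e-07 (adjusted p = 0.15 with an estimated correlation). All 18 dendritic cell maturation genes rose (18 adjusted over the list alone), including the costimulator Cd40 (4.79) and Il15 (3.83). All 18 MHC class I genes rose too (18 adjusted over the list alone), led by their transactivator Nlrc5 (3.61) and the peptide transporter gene Tap1 (2.39). The camera adjusted p of these lists was 1.11e-10 and 3.49e-11 (adjusted p = 0.0903 with an estimated correlation for both). MHC class II did not move as a list (6 rose and 1 fell of 12, 7 adjusted over the list alone, camera adjusted p = 0.307), with Ciita at 1.19 and H2-DMa at -0.58. Of 20 TLR4 signalling genes, 14 rose and 4 fell (18 adjusted over the list alone; camera adjusted p = 0.000545, adjusted p = 0.179 with an estimated correlation).

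Genes of the cell cycle fell. Of 25, 23 were lower and 1 higher at 4 h (24 adjusted over the list alone), with the mitotic genes Cdc20 at -2.74 ± 0.30 and Plk1 at -2.34 (camera adjusted p = 4.8e-05, adjusted p = 0.574 with an estimated correlation). Of 25 heterochromatin and TE silencing genes, 6 rose and 11 fell (17 adjusted over the list alone; camera adjusted p = 0.858). The histone chaperone gene Daxx rose by 3.66 and Morc3 by 1.81, whereas the maintenance DNA methyltransferase gene Dnmt1 fell by 1.61, the heterochromatin protein gene Cbx3 by 1.64, and Suv39h1 by 0.59 ± 0.15. Among 18 glycolysis and HIF target genes 8 rose and 1 fell (9 adjusted over the list alone; camera adjusted p = 0.0378, adjusted p = 0.556 with an estimated correlation). Of 20 cholesterol synthesis genes 12 rose, with Idi1 at 1.83, and 3 fell, with Dhcr7 at -1.88 (15 adjusted over the list alone; camera adjusted p = 0.205). Of 10 replication-dependent histone genes, 1 rose and 3 fell (4 adjusted over the list alone; camera adjusted p = 0.643).

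Markers of single cell types moved in both directions at 4 h, and none of these lists passed the camera test. Among 16 macrophage markers 4 rose and 3 fell (7 adjusted over the list alone, camera adjusted p = 0.879), with the scavenger receptor genes Marco at 2.82 and Cd163 at -2.93. Among 16 conventional dendritic cell markers 6 rose and 4 fell (10 adjusted over the list alone), with Xcr1, the receptor of the cross-presenting subset, at 3.64. The median of this list was -0.06, while its mean (0.12) and test were above 0 (camera adjusted p = 0.643). Mast cell and basophil markers (9 tested) gave 2 higher and 1 lower (3 adjusted over the list alone, camera adjusted p = 0.695), with the histidine decarboxylase gene Hdc at 4.65 and Il1rl1 at -3.04. Plasmacytoid dendritic cell markers gave 5 higher and 1 lower of 10 (6 adjusted over the list alone, camera adjusted p = 0.205). Granulocyte markers gave 1 higher and 1 lower of 14 (2 adjusted over the list alone, camera adjusted p = 0.858). B cell markers gave 1 higher and 1 lower of 9 (2 adjusted over the list alone), and T and NK cell markers 2 higher and 1 lower of 9 (2 adjusted over the list alone), both with a camera adjusted p of 0.879. Of 5 erythroid and megakaryocyte markers 1 rose (0 adjusted over the list alone, camera adjusted p = 0.879). Of 10 fibroblast and stroma markers 1 rose (1 adjusted over the list alone, camera adjusted p = 0.739).

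The baseline of each knockout was compared with wild-type cells to see how they differed before LPS (3 libraries against 6). MyD88KO cells differed in 9 genes. The transcription factor gene Tfcp2l1 was higher by 9.84 ± 0.42 and the chemokine receptor gene Xcr1 by 2.75 ± 0.22, while Myd88 was lower (-0.66 ± 0.09), as were Cxcl1 (-3.21 ± 0.59), Ccr9 (-2.74 ± 0.48) and Glb1 (-0.60). Of the 8 called genes other than Myd88, 4 (Glb1, Xcr1, Tgfbr2 and Ccr9) lay within 20 Mb of Myd88, where 248 of 14124 tested genes lie (GENCODE positions). No ISG passed over all genes, but 21 of 42 were lower adjusted over the list alone, with a median of -0.97 (camera adjusted p = 4.18e-33, adjusted p = 0.0754 with an estimated correlation). All MyD88KO libraries belong to the low set of library numbers, which differed at 0 h from the high set in 48 genes of wild-type cells. Against the 3 wild-type libraries of the low set 2 genes differed, and 0 of 42 ISGs adjusted over the list alone, with a median of -0.57 (camera adjusted p = 7.14e-36, adjusted p = 0.0586 with an estimated correlation). The 23 cytokine genes were lower as a list against this set, with a median of -0.48, and -0.80 against all wild-type libraries. Within the set their camera adjusted p was 1.31e-10 (0.0062 with an estimated correlation), with 1 lower adjusted over the list alone. Against all wild-type libraries DESeq2 called 43 genes (5 higher, 38 lower). TrifKO cells differed from wild-type cells in 0 genes by edgeR, with 515 at an unadjusted p under 0.05, and in 0 by DESeq2. Their 25 cell cycle genes as a list were lower (camera adjusted p = 6.7e-10, adjusted p = 0.617 with an estimated correlation), with a median of -0.42, or -0.29 against the high set alone. TE subfamilies differed in 0 cases at baseline in either knockout by edgeR, with 64 (MyD88KO) and 21 (TrifKO) at an unadjusted p under 0.05 and 0 in both by DESeq2.

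Without MyD88, LPS still induced interferon genes. In MyD88KO cells Cxcl10 rose by 6.54 ± 0.50 at 2 h and 7.70 ± 0.53 at 4 h, and Ifit1 by 5.40 ± 0.66 and 7.77 ± 0.73 (3 libraries against 3). Of 42 ISGs 29 rose at 2 h (33 adjusted over the list alone) and 42 at 4 h (42 adjusted over the list alone; camera adjusted p = 1.4e-52, adjusted p = 0.0317 with an estimated correlation). Of 23 cytokine genes 15 rose at 2 h (20 adjusted over the list alone) and 16 at 4 h (18 adjusted over the list alone), with Il1b at 5.01 ± 0.43 and 3.43 ± 0.40. All 18 MHC class I genes and 17 of 18 maturation genes rose at 4 h (18 and 17 adjusted over the list alone). In all 2326 genes were called at 2 h and 4931 at 4 h.

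Without TRIF the order was inverted, and inflammatory genes rose while interferon genes lagged. In TrifKO cells Cxcl1 rose by 7.31 ± 0.54 and Ptgs2 by 6.74 ± 0.62 at 2 h, whereas Cxcl10 rose by 2.02 ± 0.41. Of 23 cytokine genes 22 rose at 2 h (22 adjusted over the list alone; camera adjusted p = 3.23e-26, adjusted p = 0.0247 with an estimated correlation) and 21 at 4 h (22 adjusted over the list alone). Of 42 ISGs 5 rose at 2 h (4 adjusted over the list alone; camera adjusted p = 0.17), among them Ifi205 at 3.94 ± 0.44. At 4 h 29 rose with a median of 1.41 (32 adjusted over the list alone; camera adjusted p = 1.32e-11, adjusted p = 0.443 with an estimated correlation). MHC class I genes rose in 5 of 18 cases at 4 h (5 adjusted over the list alone; camera adjusted p = 0.00923, adjusted p = 0.835 with an estimated correlation). The mast cell protease gene Cpa3 was 4.85 ± 1.61 higher at 4 h, but -0.19 without TrifKO 4 h replicate 3. In all 2997 genes were called at 2 h and 3746 at 4 h.

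The difference between the MyD88KO and the wild-type response asks which part of the response needs MyD88. Ptgs2 rose less by 4.43 ± 0.65 at 2 h, so its log2 difference was -4.43, and Cxcl1 (-4.38 ± 0.91), Il6 (-3.71 ± 0.61) and Ccl3 (-3.65 ± 0.78) also fell behind. At 4 h the Notch ligand gene Dll4 (-6.94 ± 1.26), Cxcl1 (-5.86 ± 0.98), Ptgs2 (-5.76 ± 0.67, 54.1-fold) and Nos2 (-5.23 ± 1.21) were the strongest of these, and Neurl1b (2.69 ± 0.38) and the mitotic gene Aspm (2.41) went the other way. Of 23 cytokine genes 5 had a smaller response at 2 h (14 adjusted over the list alone; camera adjusted p = 2.79e-33, adjusted p = 0.00946 with an estimated correlation) and 15 at 4 h (16 adjusted over the list alone; camera adjusted p = 5.08e-27, adjusted p = 0.0271 with an estimated correlation). The median over this list at 4 h was -4.11. No ISG differed at either time over all genes (5 at 2 h and 0 at 4 h adjusted over the list alone), and their median difference at 4 h was -0.08 (camera adjusted p = 0.741). At 2 h the ISG median was -0.87 (camera adjusted p = 2.2e-12, adjusted p = 0.479 with an estimated correlation). These are differences of fold changes from the lower MyD88KO baseline given above, and levels after LPS were not tested. At 4 h Ifit1 averaged 1033 CPM in MyD88KO cells, and 1557 and 2569 in wild-type cells of the low and high set. Cxcl10 averaged 1362 CPM, and 2399 and 3546. Ifnb1 at 4 h did not pass (-0.93 ± 1.56). Among maturation genes the costimulators Cd80 (-1.52) and Cd86 (-1.25) and Slamf1 (-2.10) fell behind at 4 h, 3 of 18 (4 adjusted over the list alone; camera adjusted p = 0.000703, adjusted p = 0.66 with an estimated correlation). NF-kB genes Socs3 (-2.67) and Nfkbiz (-2.58) fell behind at 2 h, 2 of 26 (camera adjusted p = 0.00997, adjusted p = 0.733 with an estimated correlation).

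In all 64 genes differed between these responses at 2 h (8 higher, 56 lower) and 993 at 4 h (358 higher, 635 lower). Leaving out 1 library moved the first count between 19 (without MyD88KO 2 h replicate 2) and 189 (without WT 2 h replicate 1a), by over 1.5 times for 11 libraries. The second moved between 585 (without MyD88KO 0 h replicate 2) and 1291 (without WT 4 h replicate 2a), by over 1.5 times for 3. The wild-type libraries fall into a set with library numbers up to 30 in the titles, shared with MyD88KO, and a set from 33 on, shared with TrifKO. Against the wild-type libraries of their own set alone, 15 genes differed at 2 h and 88 at 4 h, and the cytokine list had 5 of 23 lower at 2 h and 10 at 4 h, with a median of -3.73. With the cohort number as a replicate block the counts were 147 and 1506.

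The difference between the TrifKO and the wild-type response asks which part needs TRIF. Ifit3b (-5.61 ± 0.68), Ifit1 (-5.47 ± 0.73) and Ifit2 (-5.15 ± 0.71), which encode interferon-induced tetratricopeptide proteins, and Cxcl10 (-4.95 ± 0.53) fell behind at 2 h. At 4 h Cxcl10 remained behind (-5.19 ± 0.53), with the interferon-induced exonuclease gene Isg20 at -5.37. Of 42 ISGs 30 had a smaller response at 2 h (41 adjusted over the list alone; median -2.30; camera adjusted p = 1.66e-102, adjusted p = 0.000395 with an estimated correlation). At 4 h all 42 did (42 adjusted over the list alone; median -3.68; camera adjusted p = 5.43e-48, adjusted p = 0.0272 with an estimated correlation). Of 7 type I interferon and IRF3 target genes 5 were behind at 2 h and 7 at 4 h (7 at both times adjusted over the list alone). Sensors were behind too, 10 of 18 at 2 h (13 adjusted over the list alone) and 14 at 4 h (15 adjusted over the list alone), with Ifih1 at -3.42 and Ddx58, the gene of the RNA sensor RIG-I, at -2.57 at 2 h. Against the wild-type libraries of their own set 26 ISGs were behind at 2 h and 42 at 4 h.

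At 4 h the effect reached antigen presentation, where 16 of 18 MHC class I genes rose less (16 adjusted over the list alone; adjusted p = 0.0272 with an estimated correlation), including H2-T22 (-2.46) and Nlrc5 (-2.43). Of 18 maturation genes 9 did so (14 adjusted over the list alone), led by Il15 (-3.11). Of 23 cytokine genes 0 differed at 2 h by edgeR (0 adjusted over the list alone; camera adjusted p = 1.95e-10, adjusted p = 0.146 with an estimated correlation). At 4 h 8 were behind (13 adjusted over the list alone; median -1.67; camera adjusted p = 1.46e-07, adjusted p = 0.269 with an estimated correlation), among them Il27 (-4.43) and Edn1 (-3.38). Of 26 NF-kB genes 15 were behind at 4 h (16 adjusted over the list alone; adjusted p = 0.188 with an estimated correlation). The fold changes of cell cycle genes were higher than in wild-type cells, from the lower baseline given above, in 9 of 25 (13 adjusted over the list alone; camera adjusted p = 7.85e-07, adjusted p = 0.446 with an estimated correlation), with Cdc20 at 2.09 and Plk1 at 1.85. Of 25 silencing genes 6 had a higher fold change, such as Uhrf1 (1.35) and Cbx3 (1.09), and 4 a lower one, such as Daxx (-2.76) and Morc3 (-1.62), with 11 adjusted over the list alone and a camera adjusted p of 0.586. In all 200 genes differed at 2 h (19 higher, 181 lower) and 2647 at 4 h (1301 higher, 1346 lower). With set and cohort as a replicate block the counts were 432 and 4757, but TrifKO libraries of a cohort number were hardly paired (mean residual correlation 0.129, lowest -0.264).

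Compared directly, the knockouts parted along the same groups of genes. Cxcl10 was -4.52 ± 0.59 in the TrifKO minus the MyD88KO response at 2 h and -5.19 ± 0.59 at 4 h, whereas Cxcl1 (4.62 ± 0.97) and Ptgs2 (3.44 ± 0.73) were higher at 4 h. Of 42 ISGs 11 were lower at 2 h (23 adjusted over the list alone; adjusted p = 0.00943 with an estimated correlation) and 41 at 4 h (42 adjusted over the list alone; camera adjusted p = 1.19e-72, adjusted p = 0.00658 with an estimated correlation). Of 23 cytokine genes 6 were higher at 4 h (8 adjusted over the list alone; camera adjusted p = 2.84e-07, adjusted p = 0.398 with an estimated correlation). The RNase gene Zc3h12a (2.08) and Socs3 (1.94) were higher at 2 h. In all 37 genes differed at 2 h and 659 at 4 h. The first count was 19 without MyD88KO 0 h replicate 3 and moved by over 1.5 times for 8 libraries. With each response set against the wild-type response of its own library set, 2 and 289 genes differed. The wild-type libraries enter both differences, so a shared part is expected. At 4 h 519 genes differed in the same direction in both knockouts and 4 in opposite directions, where 91.2 were expected for independent calls. Simulated unchanged groups shared 0, but they called at most 1 gene, so their shared count could not measure this part. The correlation of these differences across genes, which are not independent replicates, was 0.432 against 0.311 in the simulations, with 0.353 the highest of 8. With separate wild-type libraries for each knockout 35 genes were shared (10.5 expected). At 2 h 25 genes were shared (0.711 expected), and 0 with separate wild-type libraries by edgeR, with a correlation of 0.231.

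**Figure D2:**
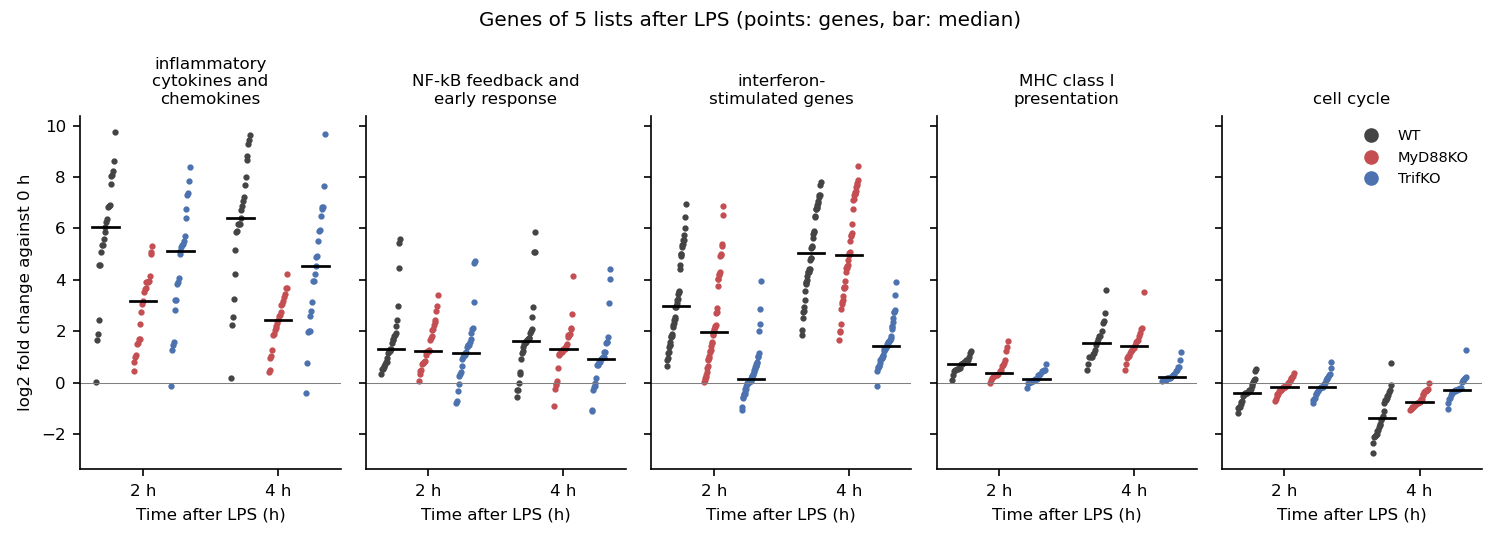
Log2 fold change against 0 h of each gene of 5 lists (points) with the list's median (bar), for wild-type, MyD88KO and TrifKO cells at 2 h and 4 h after LPS. The ISG median at 4 h was 5.05 in wild-type cells and 1.41 in TrifKO cells.

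The mean share of counts on TEs was higher after LPS in each genotype, by amounts that differed in relation to the spread between libraries. In wild-type dendritic cells TEs held 4.36% ± 0.56 (SD, n = 6) of counts at 0 h, 4.84% ± 0.80 (n = 5) at 2 h (two-sided exact permutation p = 0.299) and 5.07% ± 0.44 (n = 6) at 4 h (exact p = 0.0281, 0.32 adjusted over the 16 comparisons). LTR elements, which include endogenous retroviruses, went from 1.29% to 1.64% at 2 h (exact p = 0.0411, adjusted 0.16) and 1.73% at 4 h, where all 6 libraries lay above all at 0 h (exact p = 0.00216, the smallest possible, adjusted 0.0346). This p counts 6 separate libraries, and 3 cohorts against 3 could give no exact p under 0.1. LINE elements went from 0.708% to 0.852% at 4 h (exact p = 0.0173, adjusted 0.277), and SINE elements from 2.16% to 2.27% (exact p = 0.45). The total share was 4.13% ± 0.20, 4.48% ± 0.28 and 4.79% ± 0.02 in MyD88KO cells and 4.66% ± 0.20, 4.81% ± 0.13 and 4.99% ± 0.28 in TrifKO cells at 0 h, 2 h and 4 h (3 libraries each, where the smallest exact p is 0.1, reached in MyD88KO cells at 4 h). Without the 10 copies with most counts of each subfamily, the wild-type share was 2.75% at 0 h and 2.42% at 4 h (exact p = 0.152). These copies were picked by counts over all libraries of the experiment, LPS libraries included, so the loss of the rise is partly built in. Repeats outside the TE classes, such as satellites and repeats of unknown class, went from 0.188% to 0.140% at 4 h (exact p = 0.00216, adjusted 0.0173).

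**Figure D3:**
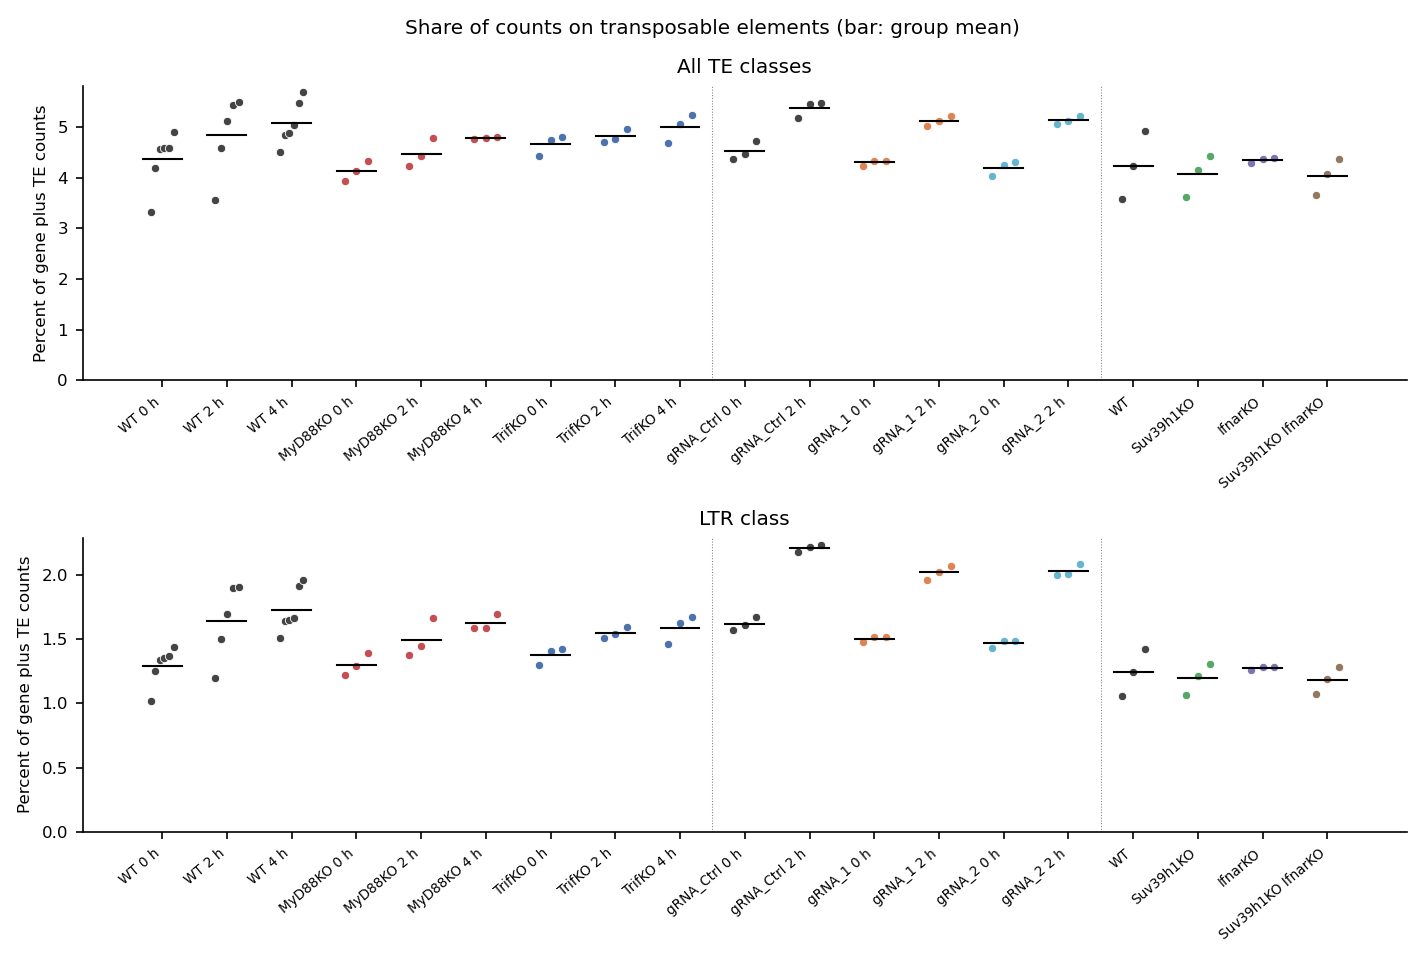
Percent of gene plus TE counts on all TEs (one panel) and on LTR elements (the other panel), with 1 point per library and a group per column. In wild-type cells the LTR share was 1.29% at 0 h and 1.73% at 4 h after LPS.

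The largest rises of TE subfamilies in wild-type cells included endogenous retroviruses and DNA elements. MMVL30-int, the internal part of the VL30 retroelement, rose by 2.69 ± 0.26 (6.47-fold) at 2 h and 3.15 ± 0.26 (8.89-fold) at 4 h, and RLTR6_Mm, its long terminal repeat, rose by 3.33 ± 0.33 and 3.78 ± 0.33. Of 99 tested MMVL30-int copies 75 rose at 2 h and 84 at 4 h. This counts copies and does not show how evenly the rise was spread over them. In TrifKO cells at 4 h 1 copy had 1060 CPM, where the subfamily averaged 2377 CPM. MER89 rose by 4.16 ± 0.22 and 5.77 ± 0.23, but 1 copy held 93.3% of its counts, and the values were 0.06 and 0.13 without its 10 fullest copies (adjusted p = 0.963 and 0.781). ERVB5_1-I_MM-int rose by 4.62 ± 0.51 and 4.95 ± 0.51 (0.32 and -0.41 without its 10 fullest copies, adjusted p = 0.808 and 0.533), and ERVB2_1-I_MM-int by 6.21 ± 0.66 (74.2-fold) at 4 h. The DNA element MamRep38 rose by 3.34 ± 0.26 and 4.67 ± 0.27 (0.79 and 1.08 without its 10 fullest copies, adjusted p = 0.489 and 0.0784), and Ricksha_0, also a DNA element, by 4.20 ± 0.45 at 4 h. The LINE element L1MB1 fell by 1.04 ± 0.16 and RLTR44-int by 1.00 ± 0.14 at 2 h, and RLTR30D_RN by 1.40 ± 0.29 and L1MB1 by 1.19 ± 0.15 at 4 h. Without their 10 fullest copies L1MB1 was 0.48 and 0.67 higher at 2 h and 4 h, and RLTR44-int was at -0.14 (adjusted p = 0.867). In all 421 of 945 subfamilies were called at 2 h (370 higher, 51 lower) and 621 at 4 h (557 higher, 64 lower).

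Most subfamilies rose when scaled by gene counts. On this scale the median subfamily was 0.28 higher at 2 h and 0.50 higher at 4 h (log2), and 89.7% of called subfamilies at 4 h were higher. Scaling by the TE counts themselves sets the median near 0 by construction, so it does not test the general direction, but it shows which subfamilies moved apart from the others, and 607 were called at 4 h. RLTR6_Mm and MER89 were higher under both scalings, RLTR6_Mm by 3.16 and MER89 by 5.19 at 4 h with the TE scaling. Among single copies, 20270 of 64924 were called at 2 h (13181 higher) and 27554 at 4 h (18461 higher). Of tested copies with adjacent running numbers, the neighbours of a copy that rose had also risen in 85.7% of cases at 4 h, against 28.4% of all copies. Without the 10 fullest copies of each subfamily, 25 subfamilies were called at 2 h and 232 at 4 h.

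MMVL30-int was 0.89 ± 0.34 and 0.68 ± 0.34 higher in MyD88KO cells at 2 h and 4 h without passing in the unpaired fit (adjusted p = 0.0987 and 0.111). The MyD88KO libraries had 369 to 441 CPM at 0 h, 529 to 855 at 2 h and 626 to 643 at 4 h. Neither time overlapped with 0 h, so the missed threshold does not show an absent rise. In TrifKO cells MMVL30-int rose by 2.37 ± 0.36 and 2.57 ± 0.36. Without its 10 fullest copies the TrifKO values were 0.94 (adjusted p = 0.502) and 1.08 (adjusted p = 0.197). In TrifKO cohort 3, where Ticam1 was low, MMVL30-int had 1067 CPM at 2 h and 1373 CPM at 4 h, less than in the other TrifKO libraries (2421 and 2698 at 2 h, 2739 and 3019 at 4 h) and in every wild-type library of these times (from 1372 and 1905 CPM). The MyD88KO response was smaller than the wild-type response at 4 h for MMVL30-int (-2.47 ± 0.42, adjusted p = 0.000927), RLTR6_Mm (-2.34 ± 0.52), RLTR6C_Mm (-2.55 ± 0.35) and MuRRS-int (-2.28 ± 0.43). Without the 10 fullest copies MMVL30-int (-1.82, adjusted p = 0.00861) and MuRRS-int (-2.07, adjusted p = 0.00861) still passed, but RLTR6_Mm (-1.60, adjusted p = 0.0901) and RLTR6C_Mm (-1.26, adjusted p = 1.00) did not. At 2 h MMVL30-int did not pass (-1.80 ± 0.43, adjusted p = 0.0596). The TrifKO response of MMVL30-int, over all 3 cohorts, did not differ past the threshold from the wild-type one (-0.58 ± 0.42 at 4 h, adjusted p = 0.383), which does not show that the responses were alike. It exceeded the MyD88KO response (1.89 ± 0.48, adjusted p = 0.0173), but not past the threshold without its 10 fullest copies (0.72, adjusted p = 1.00).

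MER89 and ERVB2_1-I_MM-int behaved the other way. MER89 rose by 3.02 ± 0.29 and 5.26 ± 0.32 in MyD88KO cells (0.78 and 0.82 without its 10 fullest copies, adjusted p = 0.983 and 0.371), and its TrifKO response was smaller than in wild-type cells by log2 differences of -3.54 ± 0.35 at 2 h and -3.91 ± 0.35 at 4 h. These became 0.21 and 0.34 without its 10 fullest copies, so they describe a few copies. ERVB2_1-I_MM-int rose by 6.38 ± 0.97 in MyD88KO cells at 4 h, and its TrifKO minus wild-type difference was -3.74 ± 1.04 at 2 h and -4.94 ± 1.01 at 4 h. Its wild-type values ranged from 0.41 to 3.80 CPM at 0 h, 1.91 to 23.7 at 2 h and 42.3 to 244 at 4 h. The highest at 2 h (22.9 and 23.7 CPM) were those of the closely alike replicates 1b and 2b. MamRep38 (-3.31 ± 0.42, but -0.77 with an adjusted p of 0.958 without its 10 fullest copies), IAPEY3-int (-3.02 ± 0.63, but 0.20 without its 10 fullest copies) and ERVB5_1-I_MM-int (-2.95 ± 0.79, but 0.12 without them) also fell behind in TrifKO cells at 4 h. MMTV-int, a mammary tumour virus, fell at 4 h by 0.93 ± 0.22 in MyD88KO and by 1.34 ± 0.23 in TrifKO cells. Between TrifKO and MyD88KO responses at 4 h MER89 differed by -3.41 ± 0.40 (-0.35 without its 10 fullest copies, adjusted p = 1.00) and RLTR6C_Mm by 2.37 ± 0.40 (0.98 without its 10 fullest copies, adjusted p = 1.00).

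In all 73 subfamilies were called in MyD88KO cells at 2 h (66 higher) and 350 at 4 h (326 higher), and 60 (49 higher) and 98 (78 higher) in TrifKO cells. Leaving out TrifKO 0 h replicate 2 lowered the TrifKO counts to 31 and 47, and leaving out MyD88KO 0 h replicate 2 lowered the MyD88KO count at 2 h to 44. The MyD88KO response differed from the wild-type response in 1 subfamily at 2 h (MamRep38, -2.01 ± 0.41, but -0.06 without its 10 fullest copies) and in 26 at 4 h (2 higher, 24 lower). The TrifKO response differed in 22 at 2 h (all lower) and 157 at 4 h (8 higher, 149 lower). Without WT 2 h replicate 1a the counts at 2 h became 26 and 65, and without TrifKO 2 h replicate 3 the second became 8. Without MyD88KO 0 h replicate 3 the MyD88KO counts were 0 at 2 h and 13 at 4 h. Against the wild-type libraries of the same set, 0 and 5 subfamilies differed for MyD88KO and 105 and 314 for TrifKO.

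**Figure D4:**
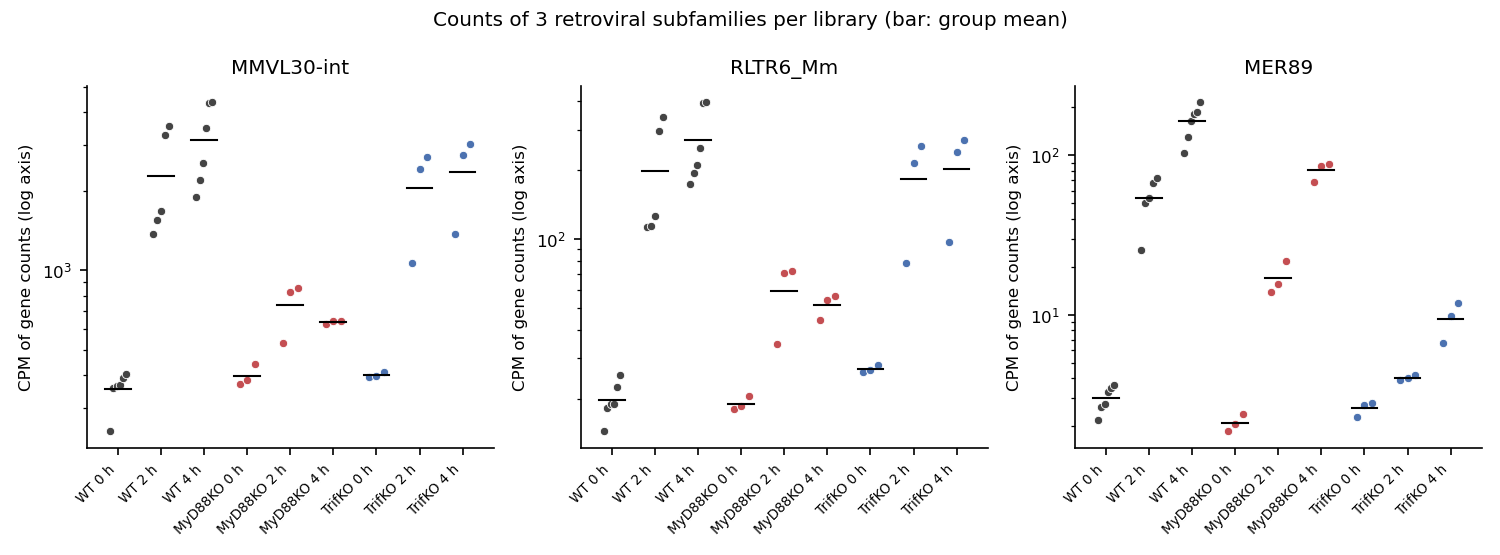
CPM (log axis) of MMVL30-int, RLTR6_Mm and MER89, with 1 point per library, in wild-type, MyD88KO and TrifKO cells at 0 h, 2 h and 4 h after LPS. MMVL30-int averaged 3143 CPM in wild-type, 637 in MyD88KO and 2377 in TrifKO cells at 4 h.

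Loss of Suv39h1 changed few genes in unstimulated dendritic cells in the unpaired fit (3 libraries against 3). Besides Suv39h1 itself (-7.80 ± 0.43 with and -7.79 ± 0.43 without a working Ifnar1), the zinc finger gene Fezf2 rose by 4.16 ± 0.24 and 4.39 ± 0.24, the neuronal Dpp6 by 4.17 ± 0.53 and 5.16 ± 0.57, and Cadps, a gene of vesicle release, by 3.99 ± 0.60 and 4.63 ± 0.61. The lipid transfer gene Pltp fell by 1.49 ± 0.17 and 1.03 ± 0.17, and Bst1 by 1.35 ± 0.15 and 1.25 ± 0.15. In all 30 genes were called with Ifnar1 intact (22 higher, 8 lower) and 32 in IfnarKO cells (27 higher, 5 lower), and 22 were called in both in the same direction (18 higher, 4 lower), where 0.0441 were expected for independent calls. Leaving out 1 library lowered these counts to between 11 (without WT replicate 1) and 20, and to between 9 (without IfnarKO replicate 2) and 23, by over 1.5 times for 5 libraries each. A replicate block raised them to 163 and 192. In this experiment the cohort number did pair libraries (mean residual correlation 0.451, against -0.222 otherwise), so the unpaired counts may be too low. The effect of Suv39h1 loss differed between the Ifnar1 genotypes in 0 genes (edgeR 101 at an unadjusted p under 0.05, DESeq2 0).

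ISGs did not move as a list on loss of Suv39h1 (0 of 41 called, 0 adjusted over the list alone, camera adjusted p = 0.566), with Iigp1 at 0.74 ± 0.62 and Ifi205 at 0.58 ± 0.67. The only list member called was Suv39h1 itself, which is in the silencing list. The camera test called the cell cycle (adjusted p = 5.33e-05), cholesterol (0.00061), MHC class II (0.00704), mast cell (0.0157) and fibroblast (0.0332) lists with Ifnar1 intact, but adjusted p = 0.797 with an estimated correlation for all except the cell cycle, which had lost its call too.

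At TEs the same knockout raised a few endogenous retroviruses. RLTR10D2 rose by 2.14 ± 0.32 (4.40-fold) with and by 2.64 ± 0.32 without Ifnar1, and IAP-d-int, of the intracisternal A particles, by 1.32 ± 0.21 and 1.53 ± 0.21. LTR67B rose by 1.55 ± 0.18 with Ifnar1, and IAP1-MM_LTR rose 2.46-fold in IfnarKO cells (adjusted p = 0.0215). With TE scaling IAP1-MM_LTR missed the threshold (adjusted p = 0.0838), although its fold was no smaller (log2 1.44). MMTV-int fell by 1.64 ± 0.21 and 1.60 ± 0.21, and RLTR3_Mm by 1.16 ± 0.21 and 1.31 ± 0.21. These were the 5 and 6 subfamilies called apart from 1 in IfnarKO cells, of 943, with 4 shared (0.017 expected). Without the 10 fullest copies of each subfamily 0 and 1 were called. Of 59202 single copies 152 were called (116 higher, 36 lower), which fell to 81 without WT replicate 2. Of these, 69 lay within a stretch of 1000 running numbers and were all higher. The TE share was 4.24% in wild-type, 4.07% in Suv39h1KO, 4.35% in IfnarKO and 4.03% in doubly deficient cells.

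Loss of Ifnar1 itself lowered the tonic interferon signature. Oas1a fell by 6.86 ± 0.46 (116-fold), Ifit3 by 5.65 ± 0.72, Ifit1 by 5.25 ± 0.64 and Irf7, the master regulator of interferon genes, by 3.64 ± 0.45, while Wdfy1 rose by 1.25 ± 0.19. Isg15 did not pass (-2.43 ± 0.58, adjusted p = 0.445). Of 41 ISGs 15 fell (35 adjusted over the list alone; camera adjusted p = 7.04e-133, adjusted p = 0.00527 with an estimated correlation), and 3 of 6 type I interferon and IRF3 targets (5 adjusted over the list alone; adjusted p = 0.00753 with an estimated correlation). In all 18 genes were called (1 higher, 17 lower), 6 without IfnarKO replicate 2. ERVB2_1-I_MM-int was the 1 subfamily called (-5.03 ± 0.87, adjusted p = 0.0227), and it was no longer called with TE scaling, where its fold was the same (-5.06, adjusted p = 0.194), or without any 1 of 5 libraries, such as WT replicate 3 (count 0).

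In RAW264.7 cells with the control guide, the 2 h samples showed a strong inflammatory response against 0 h (3 libraries each). The stimulus is given as LPS without a dose for these cells. Il1b rose by 11.77 ± 0.35, Ifnb1 by 6.56 ± 0.81 and Cxcl10 by 4.59 ± 0.25, while Bmf, a proapoptotic gene, fell by 3.83 ± 0.27, as did Cxcr4 (-3.44 ± 0.29) and Tlr4 (-1.90 ± 0.24). All 22 cytokine genes tested rose (22 adjusted over the list alone; camera adjusted p = 8.94e-19, adjusted p = 0.00395 with an estimated correlation). Of 40 ISGs 25 rose (25 adjusted over the list alone; camera adjusted p = 1.86e-06, adjusted p = 0.313 with an estimated correlation). Of 25 silencing genes 15 fell and 2 rose (18 adjusted over the list alone; camera adjusted p = 0.00194, adjusted p = 0.0191 with an estimated correlation), among them the methyltransferase genes Ehmt1 (-0.99) and Ehmt2 (-0.51) and Suv39h1 (-0.34 ± 0.06). Of 25 cell cycle genes 15 fell (15 adjusted over the list alone; camera adjusted p = 8.64e-06, adjusted p = 0.323 with an estimated correlation). In all 6743 of 13078 genes were called, and 3781 genes were called in the same direction here and in wild-type dendritic cells at 4 h (2206 expected for independent calls).

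The VL30 elements rose in this line too. MMVL30-int rose by 3.09 ± 0.09 (8.49-fold), with 149 of 162 tested copies higher, and RLTR6_Mm by 3.50 ± 0.09 (11.3-fold). MuRRS-int rose by 4.17 ± 0.47 and MER89 by 2.79 ± 0.24, and RLTR45-int fell by 0.94 ± 0.07. These subfamilies kept their direction with TE scaling and without their 10 fullest copies, where MER89 was 0.15 higher and no longer called. In all 527 of 937 subfamilies were called, 90.5% of them higher. The TE share was 4.52% at 0 h and 5.38% at 2 h, and the LTR share 1.62% and 2.21% (exact p = 0.1 for both, the smallest possible).

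Each guide was compared with the control guide at 0 h. The labels do not say whether the replicates of a guide were separately made lines. Effects of a guide, and those shared by the guides, therefore cannot be told apart from differences between lines. With guide 1 the interleukin-13 receptor gene Il13ra2 (1.60 ± 0.21), Pla2g5 (1.51 ± 0.13) and the receptor kinase gene Axl (1.13 ± 0.13) were higher, while Ly86 (-4.29 ± 0.35), a partner of a TLR homologue, and the Notch ligand gene Jag2 (-3.71 ± 0.28) were lower. With guide 2 Axl (3.15 ± 0.13, 8.91-fold), the protease gene Ctsk (2.07 ± 0.16) and Il13ra2 (1.98 ± 0.20) were higher, and Jag2 (-2.95 ± 0.26) and Jmjd1c (-1.81 ± 0.14) were lower. Of 40 ISGs 3 were lower with guide 1 (7 adjusted over the list alone; camera adjusted p = 9.87e-09, adjusted p = 0.378 with an estimated correlation), such as Oasl2 (-1.45) and Ifi44 (-1.23). With guide 2 10 were lower (12 adjusted over the list alone; camera adjusted p = 1.19e-07, adjusted p = 0.462 with an estimated correlation), such as Ifi44 (-2.02) and Irf7 (-1.49). Suv39h1 did not pass with either guide (0.13 ± 0.06 and 0.10 ± 0.06). In all 293 genes were called with guide 1 and 592 with guide 2, against 497 and 560 in a fit of only the compared groups, and 903 and 1647 with a replicate block, where the cohort number is hardly a pairing (mean residual correlation 0.123). The first count was 142 without guide 1 replicate 1 at 0 h and moved by over 1.5 times for 5 libraries, and the second was 252 without guide 2 replicate 1 at 0 h and moved so for 4. The guides shared 152 genes in the same direction (77 higher, 75 lower) and 5 in opposite directions, against 6.57 expected for independent calls. Simulated unchanged groups shared 0, but they called at most 1 gene, so their shared count tested nothing. Both guide comparisons use the same 3 control libraries, too few to split, and the covariance across genes was 0.134 against a simulated 0.0381 (highest of 10, 0.0415).

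At 2 h the same guide cells differed from control cells in 403 (guide 1) and 779 genes (guide 2). A fit of only the compared groups gave 241 and 140, and a replicate block 1240 and 2072. The first count was 181 without control replicate 1 at 2 h and moved by over 1.5 times for 3 libraries, and the second lay between 3.0e+02 (rounded to 2 digits, without control replicate 1 at 2 h) and 1213 (without guide 2 replicate 3 at 2 h) and moved so for 4. With guide 1 Il19 was higher by 6.09 ± 0.41 and Ccl2 lower by log2 -2.12 ± 0.25, and with guide 2 Axl was higher by 2.81 ± 0.12 and Trp53i11 lower (-2.01). Of 40 ISGs 6 were lower with guide 1 (17 adjusted over the list alone; camera adjusted p = 7.44e-13, adjusted p = 0.243 with an estimated correlation) and 4 with guide 2 (camera adjusted p = 0.14). The response to LPS differed from that of control cells in 1 gene for guide 1 (Sh2d5, 1.42 ± 0.19) and in 0 for guide 2 (edgeR 449 at an unadjusted p under 0.05, DESeq2 14). The first count was 0 without guide 1 replicate 1 at 0 h, and likewise for 6 other libraries. As a list the ISGs responded more with guide 2 (0 of 40 called, 0 adjusted over the list alone; camera adjusted p = 3.94e-06, adjusted p = 0.505 with an estimated correlation). ERVB4_3-I_MM-int was lower at 0 h with guide 1 (-0.75 ± 0.09) and guide 2 (-0.61 ± 0.09), and RLTR6_Mm (-0.51 ± 0.09 and -0.38 ± 0.09) and MMVL30-int (-0.49 ± 0.09 and -0.34 ± 0.09) were lower as well. With TE scaling RLTR6_Mm (-0.44) and MMVL30-int (-0.42) were not called with guide 1 (adjusted p = 0.0586 for both). In all 16 subfamilies were called with guide 1 (14 lower) and 48 with guide 2 (42 lower), with 11 shared, all lower (0.64 expected for independent calls). Simulated unchanged groups shared 0, but they called at most 1 subfamily per guide, so their shared count tested nothing. The guides share their controls, and over all subfamilies the correlation of 0.573 was within the simulated range (highest 0.601), while the covariance of 0.0359 was above it (highest 0.0247). With TE scaling, which sets the median near 0 by construction, 8 were called with guide 1 (3 higher, 5 lower) and 27 with guide 2 (17 higher, 10 lower). The lower direction of most calls therefore depends on the scaling by gene counts. The counts fell to 7 without control replicate 2 at 0 h and to 15 without guide 2 replicate 1 at 0 h. Subfamily responses to LPS differed from control cells in 0 cases for either guide by edgeR (24 and 48 at an unadjusted p under 0.05, DESeq2 0 and 1).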

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

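The split counts and the comparison of library sets were set before the results; the tests of the library labelled TrifKO 0h replicate 3 were chosen after the result was seen.

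Wild-type 4 h replicate 3a had 58.4 CPM of Ticam1, the highest of its group. It was 1 of 30 group and measure pairs tested for a library far from the others, where about 1 in 20 is expected by chance.

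Responses differed between genotypes in several comparisons. The MyD88KO minus wild-type response differed in 64 genes and 1 subfamily at 2 h and in 993 genes and 26 subfamilies at 4 h. The TrifKO minus wild-type response differed in 200 genes and 22 subfamilies at 2 h and in 2647 genes and 157 subfamilies at 4 h. The TrifKO minus MyD88KO response differed in 37 genes at 2 h and 659 at 4 h. The response with guide 1 differed from that of control cells in 1 gene, Sh2d5.

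Exchanging libraries between groups tested whether chance could give such counts of genes. In 5 comparisons no other split reached the real count: wild-type at 2 h (1 of 25, real 6641, highest other 4671) and 4 h (1 of 25, real 9426, other 7319), the TrifKO difference at 2 h (1 of 25, real 200, other 1) and 4 h (1 of 25, real 2647, other 0), and the MyD88KO difference at 4 h (1 of 25, real 993, other 427). Another split reached the real count for the MyD88KO difference at 2 h (4 of 25, real 64, other 952) and the guide 1 response (4 of 25, real 1, other 290). So it did for the TrifKO minus MyD88KO difference at 2 h (2 of 25, real 37, other 2115) and 4 h (3 of 25, real 659, other 705). For such differences of responses libraries were exchanged within each time, so a split could keep the genotypes apart at 1 time. The exchange therefore did not settle whether chance could give these counts. For the guide 2 response (25 of 25, other 164) and the Suv39h1 and Ifnar1 interaction (25 of 25, other 0) the real count was 0, which every split reaches, so the exchange tested nothing. The split with 952 exchanged libraries at 0 h alone, so the genotypes at 2 h stayed as labelled. That with 2115 exchanged all 2 h libraries of the knockouts and none at 0 h. Both hold a difference between genotypes, so their counts do not measure chance. The splits with 290 and 164 also called more than the real count, and the cause was not tested.

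For subfamilies, no other drawn split reached the real count for wild-type cells at 4 h (1 of 25, real 621, other 583), the MyD88KO difference at 4 h (1 of 25, real 26, other 1) and the TrifKO difference at 4 h (1 of 25, real 157, other 2). For genes and subfamilies alike, a share of 1 of 25 lies under 0.05 but is the smallest that the draws allow. It is not adjusted over comparisons and counts every library as separate. Another split reached the real count for wild-type cells at 2 h (2 of 25, real 421, other 488), the MyD88KO difference at 2 h (7 of 25, real 1, other 471) and the TrifKO difference at 2 h (2 of 25, real 22, other 179), so chance was not excluded there. For the Suv39h1 and Ifnar1 interaction (25 of 25, other 4) and the guide responses (25 of 25 each, other 1 and 0) the real count was 0 and nothing was tested. The split with 488 made a group of high library set samples only, and those with 471 and 179 moved wild-type 0 h replicates 1b and 2b of the high set into the knockout baseline. Wild-type cells at 0 h differed between the library sets in 137 subfamilies. The split with 488 set high set libraries apart, and that with 471 mixed the sets in the MyD88KO baseline. That with 179 left the TrifKO baseline within the high set. The cause of these counts was not tested. Within the low and the high set alone 118 and 471 subfamilies were called in wild-type cells at 2 h. For copies no other drawn split reached the real count at 2 h (1 of 25, real 20270, other 11145) and 4 h (1 of 25, real 27554, other 17049) in wild-type cells.

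Groups of 3 against 3 have only 10 splits, too few for a share under 0.05. The real count was the highest (1 of 10) for genes in MyD88KO cells (real 2326 and 4931, highest other 1 and 3), TrifKO cells (2997 and 3746, other 0), Suv39h1KO (30, other 0; 32 in IfnarKO, other 1), IfnarKO (18, other 1), RAW264.7 cells after LPS (6743, other 0), and guides at 0 h (293 and 592, other 0) and 2 h (403 and 779, other 0). It was also the highest for subfamilies in MyD88KO (73 and 350, other 0), TrifKO (60 and 98, other 0), Suv39h1KO in IfnarKO cells (6, other 1), IfnarKO (1, other 0), RAW264.7 cells (527, other 13) and guides (16 and 48, other 0), and for copies in Suv39h1KO (152, other 0). For subfamilies in Suv39h1KO with Ifnar1 intact another split called 78 against the real 5 (2 of 10), which points to a structure of the samples.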

How the results depend on the processing

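The replicate block of set and cohort, single library sets, subfamilies without their 10 fullest copies and responses against the own-set wild type were chosen after the result was seen; the others were planned. Of 45 counts 26 stayed within 1.5 times with the cohort block and 19 moved, of 42 with DESeq2 24 stayed and 18 moved, and of 42 without a filter 40 stayed and 2 moved. Counts that moved are given below, with some of the subfamilies that did, and the cause was not tested for any of them.

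DESeq2 called more. In genes it gave 195 for the MyD88KO minus wild-type response at 2 h (edgeR 64), 91 for TrifKO minus MyD88KO at 2 h (37), 126 and 134 for Suv39h1KO with and without Ifnar1 (30 and 32) and 50 for IfnarKO (18). For guides 1 and 2 it gave 531 and 944 at 0 h (293 and 592), 681 and 1205 at 2 h (403 and 779), and 7 and 14 for their responses (1 and 0). The genes shared by the guides were 267 (152). In subfamilies it gave 112 for MyD88KO at 2 h (73), 3 for the MyD88KO difference at 2 h (1), 8 and 10 for Suv39h1KO (5 and 6), 26 and 79 for the guides at 0 h (16 and 48) and 1 for the guide 2 response (0).

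The cohort number as a replicate block raised counts too. Genes were 147 and 1506 for the MyD88KO difference at 2 h and 4 h (64 and 993), 71 for TrifKO minus MyD88KO at 2 h (37), 163 and 192 for Suv39h1KO (30 and 32), 55 for IfnarKO (18), 903 and 1647 for guides at 0 h, 1240 and 2072 at 2 h, and 4 and 16 for guide responses. The guides shared 512. Subfamilies were 3 for the MyD88KO difference at 2 h, 20 and 17 for Suv39h1KO, 2 for IfnarKO, and 27 and 82 for guides. Copies in Suv39h1KO were 362 (152).

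A block of set and cohort gave in genes 4118 for MyD88KO at 2 h (2326), 5067 and 5901 for TrifKO (2997 and 3746), 413 and 2847 for the MyD88KO difference, 432 and 4757 for the TrifKO difference (200 and 2647), and 185 and 1790 for TrifKO minus MyD88KO (37 and 659). In subfamilies it gave 262 and 528 for MyD88KO (73 and 350), 200 and 256 for TrifKO (60 and 98), 19 and 76 for the MyD88KO difference (1 and 26) and 53 and 323 for the TrifKO difference (22 and 157). A term for the library set gave 56 genes for TrifKO minus MyD88KO at 2 h, and subfamilies 209 for MyD88KO at 2 h, 144 and 205 for TrifKO, 3 for the MyD88KO difference at 2 h and 280 for the TrifKO difference at 4 h.

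The low library set alone gave 3169 genes and 118 subfamilies for wild-type cells at 2 h (6641 and 421), 15 and 88 genes and 0 and 5 subfamilies for the MyD88KO difference, and 2 genes (9) between unstimulated MyD88KO and wild-type cells. The high set alone gave subfamilies 227 and 290 for TrifKO and 105 and 314 for the TrifKO difference. With wild-type libraries of a cohort summed, TrifKO minus MyD88KO had 82 and 1026 genes, and with each response against its own-set wild type 2 and 289. With wild-type libraries split by set, the covariance of the MyD88KO and TrifKO differences at 2 h was 0.0806 (0.153 with all).

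A fit of only the compared groups gave 4512 genes for TrifKO at 2 h, 35 and 659 for the MyD88KO difference, 9 and 20 for Suv39h1KO, 497 for guide 1 at 0 h, 241 for guide 1 at 2 h and 140 for guide 2 at 2 h. No filter gave 2 and 4 genes for the guide responses.

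Without the 10 fullest copies, subfamilies called were 25 and 232 in wild-type cells at 2 h and 4 h (421 and 621), 0 and 2 in MyD88KO, 0 and 4 in TrifKO, 0 and 3 for the MyD88KO difference, 0 and 1 for the TrifKO difference, 0 and 1 for Suv39h1KO, 0 for IfnarKO, 7 and 6 for guides and 1 for the guide 2 response. Of 132 values of the subfamilies that the rule makes eligible 17 stayed, 72 weakened and 43 reversed. The copies were picked by counts that include the libraries where a subfamily rose, so weaker rises are partly built in. The reversals of subfamilies in the report were ERVB5_1-I_MM-int (-0.41) and L1MB1 (0.67, and 0.48 at 2 h) in wild-type cells at 4 h, and in the TrifKO difference MER89 (0.21 at 2 h, 0.34 at 4 h), and at 4 h IAPEY3-int (0.20) and ERVB5_1-I_MM-int (0.12). Others were LTR33 (-0.0903, was 0.68) in the MyD88KO difference and MER34A1 (-0.0451, was 0.98) in the TrifKO difference at 4 h. TMM factors of TEs gave 145 subfamilies for MyD88KO at 2 h, 133 for TrifKO at 2 h, 7 and 42 for the MyD88KO and TrifKO differences at 2 h, 0 for IfnarKO, and 8 and 27 for guides.

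The percent change of the share of counts differed by class. For LTR alone it was 26.8 in wild-type cells at 2 h (10.9 for all TEs), 14.9 and 24.6 in MyD88KO (8.40 and 15.8), 12.4 and 15.2 in TrifKO (3.34 and 7.21), 36.7 in RAW264.7 cells after LPS (18.9), and -8.64 and -8.13 for guides at 2 h (-4.80 and -4.55). For SINE alone it was 5.48 in wild-type cells at 4 h (16.4), 8.16 in MyD88KO at 4 h, -0.712 in TrifKO at 2 h, 6.53 in RAW264.7 cells, and -1.27 and -1.61 for guides at 2 h. For DNA alone it was 10.05 in wild-type cells at 4 h, 1.38 and 7.22 in MyD88KO, 14.4 in RAW264.7 cells, and -2.15 and -1.26 for guides at 2 h. For LINE alone it was 24.7 in MyD88KO at 4 h and -0.503 in TrifKO at 2 h.

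Leaving out 1 library gave these ranges in genes: MyD88KO difference 19 (without MyD88KO 2 h replicate 2) to 189 (WT 2 h replicate 1a) at 2 h and 585 (MyD88KO 0 h replicate 2) to 1291 (WT 4 h replicate 2a) at 4 h; TrifKO minus MyD88KO at 2 h 19 (MyD88KO 0 h replicate 3) to 37; Suv39h1KO 11 (WT replicate 1) to 20, and in IfnarKO cells 9 (IfnarKO replicate 2) to 23; IfnarKO 6 (IfnarKO replicate 2) to 15. For guide 1 it was 142 (guide 1 replicate 1 at 0 h) to 258 at 0 h and 181 (control replicate 1 at 2 h) to 393 at 2 h. For guide 2 it was 252 (guide 2 replicate 1 at 0 h) to 671 at 0 h and 3.0e+02 (rounded to 2 digits, control replicate 1 at 2 h) to 1213 (guide 2 replicate 3 at 2 h) at 2 h, where 4 libraries moved the count by over 1.5 times. Guide responses ranged 0 to 1 and 0 to 3.

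In subfamilies the ranges were MyD88KO at 2 h 44 (MyD88KO 0 h replicate 2) to 73, TrifKO 31 to 51 at 2 h and 47 to 71 at 4 h (both lowest without TrifKO 0 h replicate 2), MyD88KO difference 0 to 26 at 2 h and 13 to 34 at 4 h (both lowest without MyD88KO 0 h replicate 3), TrifKO difference at 2 h 8 (TrifKO 2 h replicate 3) to 65 (WT 2 h replicate 1a), IfnarKO 0 to 1, guides 7 (control replicate 2 at 0 h) to 18 and 15 (guide 2 replicate 1 at 0 h) to 64, and the guide 2 response 0 to 2. Copies in Suv39h1KO ranged 81 (WT replicate 2) to 125. The share of TEs in wild-type cells changed by 5.85 (WT 0 h replicate 2a) to 18.3 percent (WT 2 h replicate 1a) at 2 h and 11.1 (WT 0 h replicate 2a) to 19.3 (WT 0 h replicate 2b) at 4 h. Cpa3 in TrifKO cells at 4 h ranged from -0.19 (TrifKO 4 h replicate 3) to 5.42.

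Alternatives that need coordinates of repeat copies were not run: copies outside gene spans, copies at least 10 kb from genes, and the intergenic share of counts.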

Other observations

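The explanations of the TrifKO label, Myd88 neighbours, the stretch of copies, the fullest copies and single subfamilies were tested after the result was seen; those of library sets, neighbouring copies and the pair of subfamily groups were written before.

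The library labelled TrifKO 0h replicate 3 had 11.7 times the Ticam1 of the other cohort 3 TrifKO libraries (mean of 2). This may come from a mislabelled or exchanged library. No partner of a swap with another TrifKO group was seen, since the lowest Ticam1 in cohorts 1 and 2 was 29.8 CPM. This does not exclude a swap, because the test takes low Ticam1 in the exchanged library for granted. Over all genes the library was close to TrifKO 0 h replicate 2 (chi-square per degree of freedom 6.53). At 2 h and 4 h replicate 3 was far from replicates 1 and 2 (194 to 253). Ticam1 is no guide to genotype in those cohorts, where the deleted part is not known. Without this library the TrifKO difference at 2 h had 135 genes in place of 200.

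The rise of TE subfamilies in wild-type cells at 4 h could reflect reads of longer transcripts that run through several copies. Log2 fold changes of copies with adjacent running numbers had a Spearman rho of 0.933 across 29259 pairs, which are not independent, against at most 0.0148 for random pairs. A few copies with most counts were not excluded as a cause: the median fold change was 0.368 without the 10 fullest copies of each subfamily (0.50 with them), which speaks against it, but the share of counts on the other copies was not higher (2.75% to 2.42%, exact p = 0.152). That share cannot decide it, since the copies left out were picked by counts that include the LPS libraries. Single subfamilies also changed beyond the general rise, since 64.1% of those tested passed with TE scaling. RLTR6_Mm was higher under both scalings and may be part of this. MMVL30-int, with many tested copies higher, may be too, but how evenly its rise was spread over copies was not shown.

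How far the smaller MyD88KO response depends on the wild-type libraries it is set against stays open. A batch effect on the wild-type response at 4 h was not excluded, although 0 genes differed between the library sets by edgeR (750 at an unadjusted p under 0.05; DESeq2 was not used for this test). Fewer than 10 genes had been set to exclude it, but this bound was wrong, since 3 libraries per set and time miss many changes and the sets differed at 0 h in 48 genes and 137 subfamilies. Of the genes called for MyD88KO at 4 h 8.46% were called again within the low set. Of them 100% kept their sign, the median absolute log2 difference went from 0.873 to 0.718, and the cytokine median from -4.11 to -3.73. Both fits hold the same MyD88KO libraries and part of the same wild-type ones, and the called genes were picked by the first fit. Kept sign and size were thus largely fixed in advance and do not show that the effect held. The standard error went from 0.213 to 0.238 with fewer libraries, so the lost calls do not show a lost effect either. For TrifKO within the high set 87.8% were called again (median 0.919 and 0.981). There the standard error fell from 0.222 to 0.205, and the wild-type replicates 1b and 2b of that set were closely alike. The high set therefore does not show what fewer libraries cost in the low set.

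The 8 genes called in unstimulated MyD88KO cells besides Myd88 lay near Myd88 more often than the tested genes (two-sided Fisher exact p = 6.15e-06). Of the copies called in Suv39h1KO cells 45.4% lay in 1 stretch of running numbers. Over 557 subfamilies that rose in wild-type cells, the MyD88KO and TrifKO differences had a Spearman rho of 0.358, against a simulated mean of 0.298 and a highest of 0.370 for groups that share wild-type libraries, and of 0.338 with separate wild-type libraries, so 2 groups of subfamilies that follow either knockout were neither shown nor excluded.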
